A study of Homo sapiens with 6 samples.

How the data were processed

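MicroRNAs (miRNAs) were measured in total RNA of HepG2 cells, an established human line that the labels describe as hepatocellular carcinoma, grown in a dextran and polyethylene glycol hydrogel. The labels name 3 samples compressed in a Flexcell system and 3 samples cultured without pressure. Group names and replicate numbers were taken from the sample titles. The sample labels, the design text and the instrument setting in the treatment protocol give 15 mmHg for 24 h, while another sentence of the same protocol gives 30 mmHg, so the dose is reported as 15 mmHg with that conflict unresolved. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

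Per the labels' protocols, RNA was purified with a miRNeasy kit and labelled with Cy3 using Agilent's miRNA kit, and each sample was read on 1 one-colour array. Per the file headers, the 6 arrays lay on 1 slide and were scanned on 1 day, and spots were quantified with Agilent Feature Extraction 10.7.1.1. In slide row 1 lay the 3 pressure arrays and control replicate 1, and row 2 held control replicates 2 and 3. The deposited scanner files hold spot intensity on a linear scale, and the processed intensity used here was background-subtracted by that software and not normalized between arrays. A deposited table of log2 values covers 2549 miRNAs and 21 control features, and how the authors made it is not given in the sources used here. Each of its columns correlated at 0.998 to 0.999 (Pearson, across miRNAs) with the log2 mean spot intensity before background subtraction, and the column medians were 4.93 to 4.94. Its scale is therefore read as log2 with no centring of miRNAs, the form of its normalization stays unknown, and it served as an alternative.

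Every array carried 50980 miRNA spots from 5893 probes, 20 spots for each of 2549 miRNAs. Control spots and the 1542 to 2040 spots per array marked as outliers were left out; 0 miRNA spots were saturated. Spots of a probe were averaged, and the probes of a miRNA, at most 4, were summed on the linear scale. The sums were divided by each array's 75th percentile over the 339 miRNAs above background on all 6 arrays, raised to a common floor of 0.0713, which is the median over arrays of the 5th percentile among miRNAs above background, and put on the log2 scale. A miRNA counted as above background on an array when some probe had a share of over 0.5 of its used spots marked well above background by the scanner software. The 383 miRNAs above background on all 3 arrays of at least 1 group were tested, of which 45 had a value at the floor on some array; such values carry no order and their fold changes are understated. In 246 tested miRNAs more than 1 probe was above background on all arrays; their probes differed by a median of 0.03 in log2 fold change, by over 0.2 in 6 miRNAs, and lay beyond 0.2 in opposite directions in 0.

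Pressure was compared with control using limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment over the 383 miRNAs and a threshold of 0.05. Fold changes are log2 values, pressure minus control, with the standard error (SE) of that model. A set of 23 miRNA lists was tested with camera at a preset correlation of 0.01, adjusted over the 16 lists with at least 3 tested members; camera with an estimated correlation and fry were run beside it. The number of miRNAs above background per array was compared with an exact two-sided permutation test over 20 assignments, whose smallest possible p is 0.1. The number of arrays limits the precision of every value.

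The lists, the tests, the alternatives and the rule for naming miRNAs were fixed before the data were examined, except where an alternative is said to have been chosen later. The rule named, in each direction, up to 10 miRNAs past the threshold whose groups did not overlap; where fewer than 5 passed, the 5 of smallest p were named as values and not as changes. It also named the 2 members of highest mean signal and the 2 of smallest p in each list, the 5 miRNAs of highest mean signal, and miR-122-5p, miR-21-5p and miR-210-3p. The alternatives covered the scaling, quantile normalization, normexp with an offset of 50, the scanner's own signal per miRNA, the deposited log2 table, filters on dim miRNAs, the floor, the use of probes, a variance trend, the replicate number and the slide row as blocks, and each array left out in turn. Removal of each array's trend on probe GC content (loess, span 0.75) and a detection limit at 1 common scaled signal were added after seeing the data.

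The steps were tested on simulated data built from the means and spreads of the 383 miRNAs. With 60 miRNAs changed, 20 per size, 78.8% of those shifted by 0.5 on the log2 scale were called, 97.1% at 1 and 100% at 2, with 0.92% of unshifted miRNAs called. With only 2 miRNAs lowered, 27% were called at -0.5, 75% at -1 and 98% at -2. A simulated list of 9 passed in 2% of 50 simulations with no shift and in 100% with a shift of -0.2, with members drawn independently. Probe positions are those of the scanner files, on GRCh37 per the file headers. The gene table used for names and overlaps is of another assembly, GRCh38.p14, and no coordinate was taken from it; 351 of the 383 tested miRNAs matched one of its miRNA genes.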

Results

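Levels of miRNAs, small RNAs that repress their target mRNAs, were measured in HepG2 cells embedded in a hydrogel. The name hepatocellular carcinoma for this line is that of the labels. RNA of 3 samples held under 15 mmHg of compression for 24 h was compared with RNA of 3 samples cultured without pressure, 1 array per sample. The comparison addressed which miRNAs of HepG2 cells respond to mechanical pressure, in a study concerned with proliferation and invasion. Of 2549 human miRNAs on the array, 339 were above background on all 6 arrays and 2115 on none. The 75th percentile of signal over those 339 miRNAs was 353 ± 12.6 intensity units on pressure arrays and 315 ± 45.0 on control arrays (SD, n = 3 each). Across miRNAs, which are not independent replicates, log2 values correlated at 0.997 to 0.998 between pressure arrays, at 0.994 to 0.996 between control arrays and at 0.990 to 0.998 between the groups (Pearson).

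Detection of miRNAs was the first comparison. Pressure arrays had 406 ± 15.5 miRNAs above background and control arrays 371 ± 9.50 (SD, n = 3 each), a difference of 34.7. The counts were 405, 391 and 422 under pressure and 362, 381 and 371 in control, so the groups did not overlap. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. Counted above 1 common scaled signal, a definition chosen after seeing the data, the difference was -1.33 (493 ± 9.87 and 494 ± 22.3, exact permutation p = 0.9). That signal, 0.0464, lies below the floor of 0.0713, so this count also takes in miRNAs not above background. Only 2 miRNAs were above background on 3 of 3 arrays of 1 group and on 0 of the other: miR-4651 and miR-6076, chosen after their values were seen, were 1.34-fold and 1.07-fold brighter under pressure. These folds set the geometric mean of scaled signal under pressure against, per control array, the higher of its lowest signal above background and the miRNA's own signal; limma's adjusted p was 0.416 and 0.785. The liver miRNA miR-122-5p was above background on 0 of 6 arrays.

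**Figure D1:**
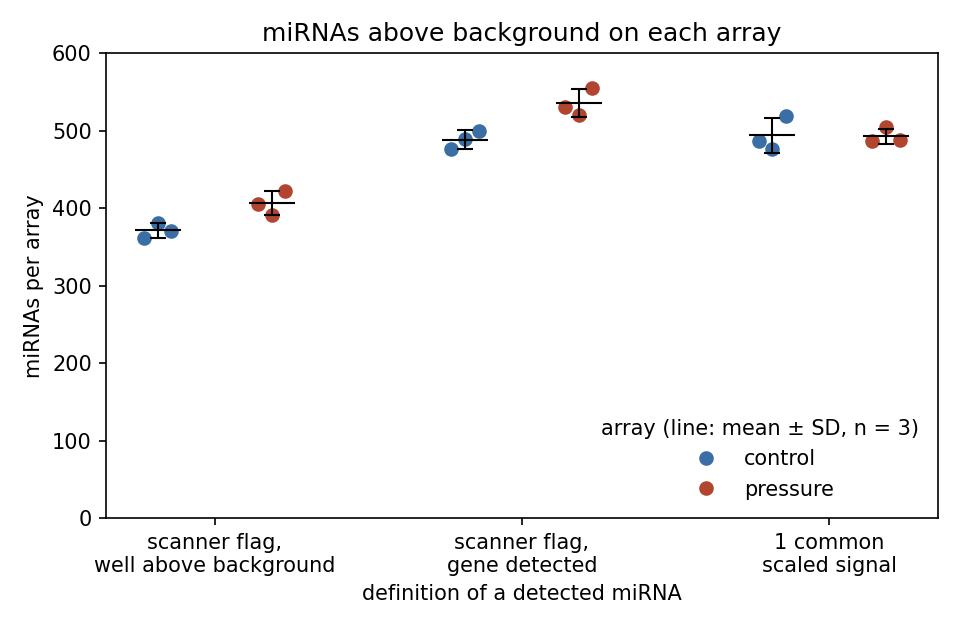
Number of miRNAs per array (vertical axis) under 3 definitions of a detected miRNA (horizontal axis) for control and pressure arrays; points are arrays, and lines are the mean ± SD of 3 arrays. By the flag for spots well above background, pressure arrays lay at 391 to 422 and control arrays at 362 to 381, whereas above 1 common scaled signal the groups overlapped. That common signal, 0.0464, lies below the floor of 0.0713.

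Single miRNAs were compared next. In the pressure samples miR-630, reported to respond to genotoxic drugs, lay at a log2 fold change of -1.09 ± 0.13 (SE) against control, and miR-5703 at -1.07 ± 0.15, which are folds of 0.471 and 0.477. Their summed signals were 45.5 ± 5.86 and 34.5 ± 5.19 intensity units under pressure against 85.4 ± 2.42 and 63.9 ± 1.97 in control (SD, n = 3 each). On the other side miR-7-5p, which represses the EGF receptor, lay at 0.50 ± 0.10, a fold of 1.41, with signals of 216 ± 9.08 and 137 ± 24.7. None of the 383 tested miRNAs passed the limma test after adjustment, with 0 higher and 0 lower at 0.05; the lowest adjusted p was 0.109 for miR-630, followed by 0.110 for miR-5703, and that of miR-7-5p was 0.135. At an unadjusted p below 0.05 in limma there were 56 miRNAs, 34 higher and 22 lower under pressure, where 19.15 would be expected by chance. The miRNAs vary together, and over the other splits of the 6 arrays into 3 and 3 this count ranged from 1 to 41. With each array left out the count at an unadjusted p below 0.05 ranged from 35 (without pressure replicate 2, and 36 without pressure replicate 3) to 79. Without control replicate 3 it split into 16 higher and 63 lower.

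The remaining miRNAs of smallest p differed by less. Lower under pressure, without passing the adjustment, were miR-574-3p at -0.31 ± 0.05 (SE), miR-505-3p at -0.23 ± 0.04 (but 0.92 with the scanner's signal per miRNA) and let-7b-5p at -0.24 ± 0.04, each with an adjusted p of 0.124. The single probe of miR-505-3p above background gave -0.13 and its groups overlapped. The other probe of miR-505-3p, above background on 0 arrays, gave -0.44. Higher were miR-4746-3p at 0.45 ± 0.10, miR-5581-5p at 0.28 ± 0.05 (but -0.011 with normexp), miR-6875-5p at 0.24 ± 0.05 and miR-6131 at 0.24 ± 0.05, with adjusted p of 0.135 to 0.172. The 3 arrays of 1 group lay apart from the 3 of the other for 74 tested miRNAs, or 19.3%, where chance gives 10% per miRNA. Pressure was above in 43 of them and below in 31. The miRNAs vary together and this share was not computed for other splits of the arrays, so an excess over chance is not established. Only miR-630 and miR-5703 reached an absolute log2 fold change of 1, and the median absolute value over all tested miRNAs was 0.09, against a median SE of 0.08. The probe of let-7b-5p maps to chromosome 22 from 46509575 to 46509592 and that of miR-505-3p to chromosome X from 139006361 to 139006378 (GRCh37). The probes of miR-630, ACCTTCCCTGGTACAGA and ACCTTCCCTGGTACAG, gave -1.10 and -1.08, and those of miR-5703, ACCTTCCCGACTTCT and ACCTTCCCGACTTCTC, gave -0.98 and -1.16.

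Processing moved the count of calls. Limma shares a variance over all 383 miRNAs, of which 45 had a value at the floor on some array. Among these, miR-181c-5p and miR-516a-5p lay at the floor on all arrays and so had no spread. With only miRNAs above background on all 6 arrays, or with the floor at the 1st percentile, 2 miRNAs passed. Whether values at the floor hold the main count at 0 was not tested. Of 23 alternative fits, miR-630 passed the adjusted threshold in 9, miR-5703 in 8 and miR-7-5p in 3, and the total ranged from 0 to 14 miRNAs. In the authors' deposited table of log2 values the fold changes were -0.55 for miR-630, -0.46 for miR-5703 and 0.37 for miR-7-5p, with limma's adjusted p of 0.0117, 0.0159 and 0.0482. Over all alternatives the adjusted p ranged from 1.85e-07 to 1 for miR-630, from 1.18e-05 to 1 for miR-5703 and from 0.00963 to 0.522 for miR-7-5p, and with each array left out in turn 0 miRNAs passed. Slide row 1 held a single control array and row 2 no pressure array, so a fit with the row as a block compares pressure with that 1 array and takes the spread from both rows. It gave -1.14 for miR-630 and -1.16 for miR-5703, with 0 miRNAs past the adjusted threshold (lowest adjusted p = 0.107) and 97 at an unadjusted p below 0.05.

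**Figure D2:**
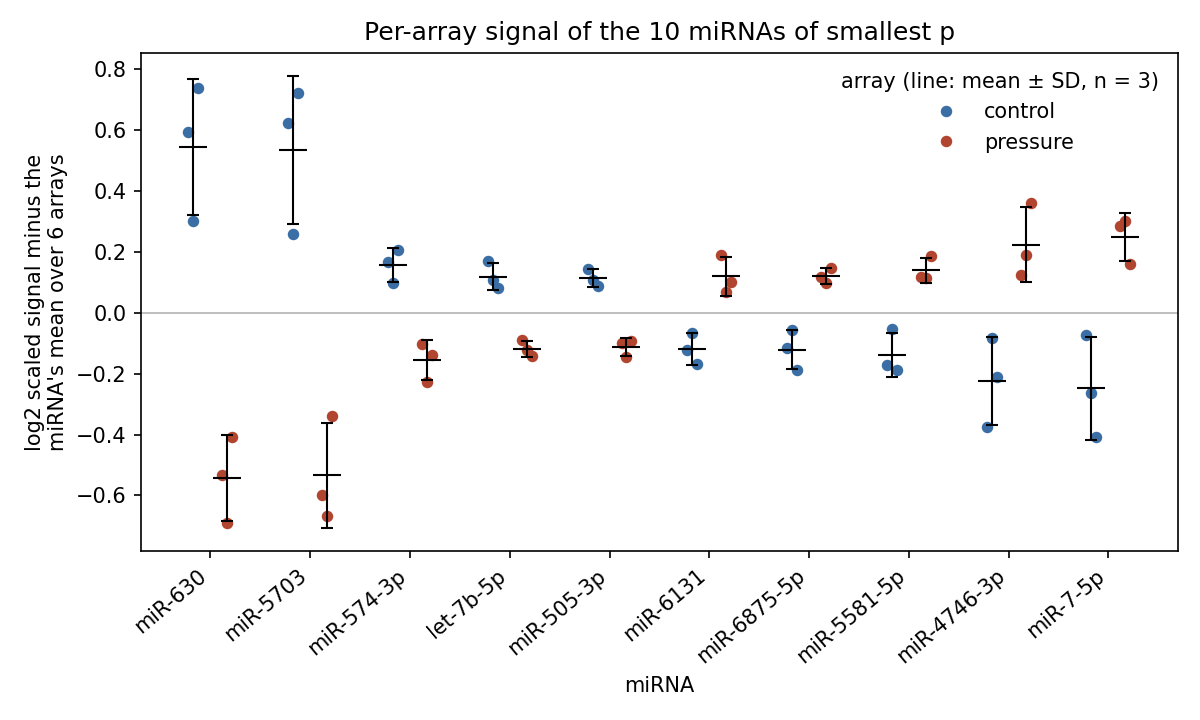
Log2 scaled signal of each array minus the miRNA's mean over the 6 arrays (vertical axis) for the 10 miRNAs named by smallest p (horizontal axis); points are arrays, and lines are the mean ± SD of 3 arrays. For each of the 10 the groups lay apart in the signal summed over probes, and miR-630 and miR-5703 had log2 fold changes of -1.09 and -1.07. For miR-505-3p the groups overlapped in the single probe above background.

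The let-7 and miR-98 family, which represses growth genes such as RAS and HMGA2, passed the set test at camera's preset correlation (adjusted p = 0.000598) but not with an estimated correlation (0.950) or with fry (0.957). All 9 tested members had a negative log2 fold change, with a median of -0.12 that ranged from -0.23 to -0.08 over the alternatives. Adjusted over all miRNAs 0 members passed, and adjusted over the list alone 1 did. After let-7b-5p, let-7c-5p lay at -0.17 ± 0.05 (SE), let-7a-5p at -0.14 ± 0.06 and let-7f-5p at -0.11 ± 0.07. Before scaling, the mean signal of let-7a-5p was 11359 ± 321 intensity units under pressure and 11256 ± 1925 in control (SD, n = 3 each), so the difference is one of level relative to the rest of the array. The camera call was also lost without control replicate 1 (adjusted p = 0.0554), with quantile normalization (0.116), with normexp (0.992) and with the scanner's signal per miRNA (0.0678); over all alternatives the adjusted p ranged from 1.64e-06 to 0.992.

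The miRNAs reported to respond to stretch, shear or compression formed the other list past the camera threshold. Of 17 tested members 16 had a negative log2 fold change and 1 a positive one, with a median of -0.07 and an adjusted p of 0.00966; the adjusted p was 0.950 with an estimated correlation. No member passed, whether adjusted over all miRNAs or adjusted over the list alone (0 and 0). miR-126-3p, an endothelial miRNA encoded in an intron of EGFL7, lay at -0.33 ± 0.08 (SE), and miR-92a-3p, a member of the miR-17~92 cluster, at -0.20 ± 0.07. The bright members miR-21-5p and miR-24-3p lay at -0.12 ± 0.08 and -0.07 ± 0.06, the former at 0.014 in the deposited table. The probe of miR-21-5p maps to chromosome 17 from 57918637 to 57918655 and that of miR-126-3p to chromosome 9 from 139565110 to 139565126 (GRCh37). This call was lost without pressure replicate 3 (adjusted p = 0.0962), without control replicate 1 (0.104) and without control replicate 2 (0.0520), and in 7 further alternatives, with a range from 3.4e-05 to 0.992; its median ranged from -0.16 to -0.03 over the 25 alternatives.

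**Figure D3:**
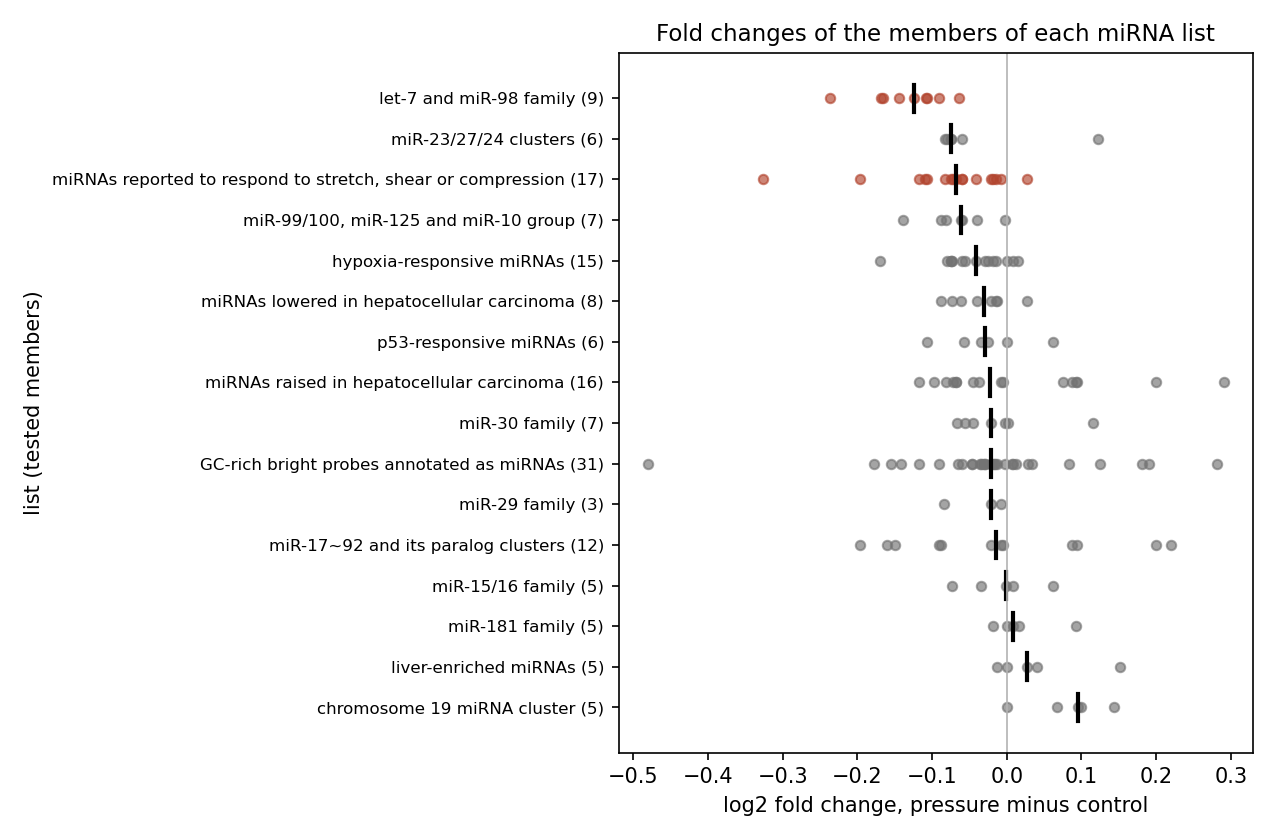
Log2 fold change, pressure minus control (horizontal axis), of each tested member of the 16 tested lists (vertical axis, with the number of members); points are miRNAs, black bars are medians, and the lists past the camera threshold at the preset correlation are in red. The let-7 and miR-98 family has 9 of 9 members below 0 and the stretch, shear or compression list 16 of 17.

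The other 14 tested lists did not pass, although 9 of them passed in 1 to 3 of the 25 alternatives. Of 15 tested hypoxia-responsive miRNAs 12 lay below 0, 2 above and 1 at the floor on all arrays (median -0.04, camera adjusted p = 0.172); miR-210-3p, the main target of hypoxia-inducible factor among miRNAs, lay at -0.17 ± 0.06 (SE, limma adjusted p = 0.306), miR-23a-3p at -0.07 and miR-27a-3p at -0.08. The hypoxia list passed with the slide row as a block (median -0.15, adjusted p = 0.00187), without control replicate 3 (-0.14, 0.00123) and without pressure replicate 1 (-0.06, 0.0393), and its adjusted p over all alternatives reached 0.992. Without control replicate 3 the miR-23/27/24 clusters (median -0.16, adjusted p = 0.0238), the miR-99/100, miR-125 and miR-10 group (-0.15, 0.00432) and the miRNAs lowered in hepatocellular carcinoma (-0.12, 0.00834) passed as well; each reached 0.992 in another alternative. These calls used camera's preset correlation. With all arrays and an estimated correlation each of these 4 lists had a camera adjusted p of 0.950. An estimated correlation was not run in those alternatives. The 4 lists share members, so their calls are not independent. A trend with signal strength was not tested for these 4 lists. Both the hypoxia list and the miR-23/27/24 clusters hold miR-23a-3p and miR-27a-3p. Both the miR-99/100, miR-125 and miR-10 group and the list lowered in hepatocellular carcinoma hold miR-100-5p and miR-125b-5p. All 7 members of the miR-99/100, miR-125 and miR-10 group lay below 0 (median -0.06, adjusted p = 0.172), with miR-125a-5p at -0.14 and miR-100-5p at -0.09. In the miR-23/27/24 clusters 5 of 6 lay below 0 (median -0.07, adjusted p = 0.396). Of the p53-responsive miRNAs 5 of 6 lay below 0 (median -0.03, but 0.0020 with the scanner's signal; adjusted p = 0.556), with miR-34a-5p at -0.11 ± 0.05. The miR-17~92 cluster and its paralogs went both ways, with 4 members higher and 8 lower (median -0.01, but 0.017 with the scanner's signal; adjusted p = 0.747); miR-18a-5p lay at 0.20 ± 0.06 and miR-18b-5p at 0.22 ± 0.06, and miR-20a-5p at -0.15 ± 0.07.

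Several families lay near 0, and their medians took both signs over the alternatives, from -0.15 to 0.030 (miR-15/16), -0.097 to 0.0098 (miR-29), -0.15 to 0.019 (miR-30) and -0.053 to 0.025 (miR-181). The miR-15/16 family had 2 of 5 members higher and 3 lower (median -0.0015, adjusted p = 0.815), with miR-16-5p at -0.03 ± 0.07. The miR-29 family had 0 higher and 3 lower (median -0.02, adjusted p = 0.556), with miR-29a-3p at -0.08 ± 0.05. The miR-30 family had 2 of 7 higher and 5 lower (median -0.02, adjusted p = 0.815), with miR-30e-5p at 0.12 ± 0.04. In the miR-181 family 3 of 5 lay above 0 and 1 below (median 0.0088, adjusted p = 0.815), with miR-181a-5p at 0.0088 ± 0.079. In the chromosome 19 cluster, normally active in placenta, 4 of 5 tested members lay above 0 and the remaining one was at the floor on all arrays (median 0.10, but -0.063 with normexp; adjusted p = 0.444); miR-521 lay at 0.14 ± 0.07.

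Liver and tumour lists showed no shift past the threshold. Of 12 liver-enriched miRNAs 5 were tested, 3 higher and 2 lower (median 0.03, with a range of -0.090 to 0.058 over the alternatives, positive in 16 of 25 and at 0 in 2; adjusted p = 0.670), with miR-152-3p at 0.15 ± 0.06 and miR-378a-3p at 0.04 ± 0.07. Of miRNAs raised in hepatocellular carcinoma 6 were higher and 10 lower; the median was -0.02, but 0.025 with the scanner's signal, while the mean was 0.015 and camera pointed upward (adjusted p = 0.997, but 3.02e-05 without a filter on dim miRNAs and 0.0462, with a median of -0.12, with the slide row as a block). Both of these calls used camera's preset correlation, and without the filter the list's median was -0.0073. With all arrays and an estimated correlation of 0.540 camera's adjusted p for this list was 0.999. An estimated correlation was not run in those alternatives. The list's member miR-301a-3p lay at 0.29 ± 0.08, or -0.039 with normexp, and its single probe above background gave 0.14. Another member, miR-25-3p, lay at -0.0045 ± 0.064. Of miRNAs lowered in hepatocellular carcinoma 1 was higher and 7 lower (median -0.03, but 0.00031 with the scanner's signal; adjusted p = 0.444), with miR-125b-5p at -0.06 ± 0.06. The GC-rich bright probes annotated as miRNAs had 10 of 31 higher and 21 lower (median -0.02, with a range of -0.12 to 0.10 over the alternatives, the highest with the slide row as a block; adjusted p = 0.556, with a range of 3.27e-05, without a filter on dim miRNAs, to 0.992); their members miR-5787 and miR-6085 lay at -0.48 ± 0.15 and 0.28 ± 0.12, with adjusted p of 0.265 and 0.385. The GC-rich call without the filter used the preset correlation, and the list's median there was -0.021. With all arrays and an estimated correlation of 0.774 camera's adjusted p for the GC-rich list was 0.950. Adjusted over the list alone, 0 members passed in each of these 14 lists.

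Markers of other cell types were mostly not above background. The miR-200 family with miR-205 (8 members), the blood cell list (8), the fibroblast and stromal list (7) and the muscle list (7) had 0 members tested, and all of these members were above background on 0 of 6 arrays. One endothelial miRNA, miR-126-3p, and one neural miRNA, miR-128-3p at -0.0075 ± 0.079, were tested. With a single tested member an adjustment changes nothing, so adjusted over the list alone miR-126-3p and miR-494-3p passed and miR-128-3p did not. Of 27 miRNAs of the imprinted chromosome 14 cluster 26 were above background on 0 arrays, and the single tested member, miR-494-3p, lay at 0.37 ± 0.13 with signals of 5456 ± 692 and 3812 ± 1088 intensity units under pressure and in control (SD, n = 3 each; limma adjusted p = 0.293). Of the miRNAs of highest mean signal, miR-7975 lay at 0.18 ± 0.22 and miR-7977 at 0.16 ± 0.21, each with an SE larger than the fold change. Over the alternatives the fold changes of miR-7975, miR-7977, miR-16-5p, miR-23a-3p, miR-25-3p, miR-128-3p, miR-152-3p, miR-181a-5p, miR-378a-3p and miR-521 took both signs.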

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

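The test of probe GC content and the count above 1 common signal in this part were chosen after the detection counts had been seen. Among the miRNAs that did not enter the test, 32 were above background on at least 1 pressure array and on no control array, against 3 the other way round. These are counts by a limit set on each array, not levels of signal. The same direction held for all miRNAs, with 34.7 more above background per pressure array. Array brightness, with a detection limit set separately for each array, is a candidate explanation that stays open. Above 1 common scaled signal the lowest pressure array lay at -33 miRNAs relative to the highest control array, so the groups no longer separated. That signal, 0.0464, lies below the floor of 0.0713. It counted 476 to 519 miRNAs per array, against 362 to 422 above background. The count therefore takes in miRNAs not above background, and it cannot decide whether brightness made the difference. Brightness alone did not order the arrays, since control replicate 2, with the highest 75th percentile (367), had 381 miRNAs above background and pressure replicate 2, at 338, had 391. A probe GC trend between arrays stays open: the arrays' correlations of deviation with GC content overlapped between the groups, with a separation of -0.74, but the overlap rests on control replicate 3, without which the groups lay apart by 0.073. A response of the cells to pressure stays open and was not tested beyond these counts.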

How the results depend on the processing

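The removal of the GC trend and the count at 1 common signal were chosen after seeing the data. The cause of a move was not tested except where stated. The count of 0 miRNAs past the adjusted threshold became 14 with normexp, which gave every miRNA the same SE of 0.07, 12 with the GC trend removed (5 higher, 7 lower), 3 in the deposited table, and 2 each with miRNAs above background on all 6 arrays, with the floor at the 1st percentile, with the brightest probe, with the mean of log2 probe values, and at an unadjusted p below 0.05 with a log2 fold change of at least 1. Detection by the scanner's flag per miRNA gave 3 (miR-630, and miR-335-3p and miR-503-5p, chosen after their values were seen), and miRNAs above background on at least 1 array gave 1 (miR-335-3p). Each array left out gave 0 to 0. With miRNAs above background on all 6 arrays and with the floor at the 1st percentile, miR-630 and miR-5703 stayed at -1.09 and -1.07. Limma's prior degrees of freedom, which weigh the variance shared by all miRNAs, rose there from 1.51 to 3.98 and 6.65. In these 2 settings the calls thus came without a move of the fold change. The prior was not higher in every setting with calls, being 1.14 with the scanner's flag per miRNA. With the replicate block 2 passed and 80 had an unadjusted p below 0.05. Same-numbered arrays correlated at 0.46, -0.11 and 0.55 in their deviations. Pressure replicates 1 and 3 correlated best with the control of the same number, and pressure replicate 2 best with control replicate 1 (0.32). Deviations taken within only 3 arrays cannot show whether the numbers pair the samples, so that stays open. The 2 lists past the camera threshold became 0 with quantile normalization, normexp, the scanner's signal per miRNA, the estimated correlation and fry. They became 1 with the scanner's flag, 6 without a filter on dim miRNAs and 7 with the slide row as a block. With each array left out the count was 0 to 6: 0 without control replicate 1, 1 without control replicate 2, 1 without pressure replicate 3 and 6 without control replicate 3. Without the filter camera gave 5 lists as higher and 1 as lower, set against all 2549 miRNAs, of which 2115 were above background on none. The medians of those 5 were -0.0060, -0.022, 0.0044, -0.0073 and -0.021, against a median of 0 over all 2549 miRNAs. Higher is therefore only the direction camera gave. By median fold change all of those lists but the miR-181 family lay below the miRNAs as a whole. The difference in miRNAs above background, 34.7, was -1.33 above 1 common signal and 26.7 to 42.2 with each array left out. The fold change of miR-505-3p reversed to 0.92 with the scanner's signal per miRNA, and the median of the chromosome 19 list to -0.063 with normexp; a value not past the threshold counted as reversed only where both values exceeded 1 SE. The let-7 and stretch lists kept a negative median in all 25 alternatives. The split at an unadjusted p below 0.05, 34 higher and 22 lower, became 28 and 11 with the percentile over all probes, 26 and 24 with quantile normalization, 14 and 51 with the brightest probe, 59 and 38 with the slide row as a block, and 16 and 63 without control replicate 3; with each array left out the total ranged from 35 to 79. A scan-date block was not run, as there was 1 scan day. Dim miRNAs limit the precision: with the floor 4 times higher miR-630 lay at -0.04 and miR-5703 at the floor on all arrays.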

Other observations

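The tests of variation and of signal strength for the let-7 family and the split of arrays for the count of 0 were chosen after their results had been seen, and the removal of the GC trend after the data had been seen. The miRNA genes that overlap another small RNA or a pseudogene in the RefSeq table (GRCh38.p14) hold 9 tested members with a median log2 fold change of 0.07. Picked after their values were seen, miR-4485-3p and miR-1973, whose genes overlap the pseudogenes MTRNR2L8 and MTRNR2L13 that resemble mitochondrial ribosomal RNA, lay at 0.47 ± 0.12 and 0.43 ± 0.15 (SE, limma adjusted p = 0.175 and 0.301). The other arm of the first precursor, miR-4485-5p, lay at -0.0082 ± 0.061. Of the snoRNA overlaps, miR-3651 lay at -0.15 ± 0.07 and miR-664b-3p at 0.09 ± 0.11. As a set the 9 lay at percentile 86.3 of 10000 lists matched on mean signal, inside the range of -0.07 to 0.12 that holds 95% of them, so a joint shift of such probes was not seen. Over 29 precursors with both arms tested, Spearman's rho between the arms' fold changes was 0.062 (permutation p = 0.763, across precursors, which are not independent replicates), so a joint shift of the arms was not seen either.

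The lower level of miR-630 and miR-5703 under pressure was followed up first. A defect of a single probe is argued against, because the probe closest to 0 still gave -0.98, and a probe GC trend is argued against, because after its removal the smaller fold change was -1.09. A shared target is a candidate explanation: the listed probe sequences of both miRNAs begin with the same 8 bases, ACCTTCCC, and they are the only 2 miRNAs on the array of which this is true. Within groups, over the 6 arrays, miR-5703 correlated with miR-630 at 0.97, the 100th percentile among 376 tested miRNAs set against miR-630. Part of this can come from the scaling. In control the unscaled signals were 83.6, 84.4 and 88.2 for miR-630 and 64.2, 61.8 and 65.6 for miR-5703. The 75th percentiles that divided them were 296, 367 and 283. The probes may report 1 RNA rather than 2, which these values do not settle. Joint regulation of both miRNAs, which the same correlation would show, stays open, and so does a response to pressure.

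The lower let-7 family was followed up next. A probe GC trend is argued against, since the median was -0.14 after its removal. Members that vary together may make the camera p too small: the residual correlation among them was estimated at 0.905, and with it the p was 0.202. A trend with signal strength stays open. The test first set for it put the family's median at percentile 0.30 of 10000 lists matched on mean signal, which met the bound against such a trend, but those lists draw unrelated miRNAs and the correlation of 0.905 makes the family's median vary more than theirs, so it decides nothing. In the test that replaced it, each array's family mean minus that of signal-matched miRNAs overlapped between the groups, with a separation of -0.025 and a difference of -0.12 ± 0.06 (SE over arrays). Near-identical sequences, which let 1 RNA bind the probes of several members, and a response to pressure stay open and were not told apart by these tests.

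The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For miRNAs past the adjusted threshold the real split gave 0 and the highest other 0, reached in 10 splits. At an unadjusted p below 0.05 the real split gave 56 and the highest other 41, so 1 split reached the real count. For lists past the camera threshold the real split gave 2 and the highest other 14, with 7 splits at 2 or more.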
